A study of Homo sapiens with 24 samples.

How the data were processed

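Expression was measured in C4-2B cells on 24 Illumina bead arrays, 1 RNA sample per array. Per the labels, cells were kept for 3 days in phenol-red-free medium with 5% charcoal-stripped serum, given 1 of 3 siRNAs (non-specific, EP300 or CREBBP), and harvested without DHT or 16 h after 10 nM DHT. Grouping by siRNA and DHT time gave 6 groups of 4 arrays, and 0 data columns were left without a group. The labels number the replicates but do not say whether they were separate cultures, so p-values measure the spread between these samples.

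The deposited signal table held the mean bead intensity of each probe, not normalised, for 48118 rows, of which 887 control rows were left out. Beside each intensity the file headers name a detection p-value, and the deposited p-value of each probe moved in steps of 1 in 770, so that it ranks the probe against negative control beads. The authors' processed values for 47231 probes were on a log2 scale, per the labels after processing that names limma without a version. They correlated with the log2 of the same array's own signal at r = 0.980 or more and with the values computed here at r = 0.998 or more, and 24 of 24 columns matched their own array best. Column medians of the authors' log2 values lay between 5.45 and 5.47.

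Signals were background-corrected and quantile normalised with neqc of limma 3.58.1 in R 4.3.3, with detection p-values in place of negative controls and an offset of 16, and taken to log2. Probes with a detection p under 0.05 on at least 4 of 24 arrays were kept, 23038 in all. Symbols came from the probe table given for this platform, brought to current symbols by Entrez identifier for 30074 of 47231 probes. Of the kept probes 16655 named 1 gene, 4 named several and 6379 named none; the last 2 kinds were left out of gene tests. For the 3279 genes with more than 1 kept probe, the brightest was used, and 12438 genes were tested.

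A single limma fit with 6 group means (18 residual degrees of freedom, trend and robust options off) gave 11 contrasts: DHT in each arm, sip300 and siCBP against siNS without and with DHT, sip300 against siCBP with DHT, and 3 differences of DHT responses. Tests were 2-sided with Benjamini-Hochberg adjustment within each contrast, and genes were called at an adjusted p under 0.05. A set of 18 gene lists was tested with limma camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over 198 tests, and again with an estimated correlation and with fry. The lists were androgen-induced, androgen-repressed, cholesterol and fatty acid synthesis, cell cycle, p53 targets, endoplasmic reticulum chaperones, ATF4 and amino acid response, interferon response, NF-kB and inflammation, hypoxia and glycolysis, CREB and immediate early genes, acetyltransferases and receptor coregulators, polyamine synthesis, and markers of luminal prostate, basal epithelium, stroma, leukocytes and neuroendocrine cells. List members were also counted after adjustment over the list alone. Lists, contrasts, tests and the rule for naming genes were chosen before the data were examined.

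Genes were named by this rule: up to 10 called genes with the largest change each way whose arrays did not overlap between the groups compared and that were detected on all 4 arrays of a group, up to 4 members of each list, and EP300, CREBBP, KLK3, KLK2, TMPRSS2 and FKBP5 in every contrast. Further items of the rule are not reported here. Genes outside it are stated as chosen after their values were seen. The mean log2 of the androgen-induced list was tested by exact 2-sided permutation of arrays, 70 arrangements within an arm and all 4900 arrangements between arms in place of the random draws first planned, with Benjamini-Hochberg adjustment over 12 tests. The share of the DHT response retained was the slope through the origin over genes called in the third arm, with a jackknife over arrays.

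Whether replicate numbers pair the samples was checked on values centred within groups. The 60 pairs of arrays with the same number correlated at 0.150 to 0.596 (median 0.335), against a median of -0.140 and at most 0.246 for different numbers, and 24 of 24 arrays lay closest to their own number. The pairing thus comes from the data, as the labels give only the numbers. Replicate number accounted for 25.8% of the variation in the values computed here and 2.18% in the authors' values, slide for 5.96%, and group for 42.4% and 60.6%. Of the difference between both versions 96.8% followed replicate number. No label states such an adjustment, and a fit to the authors' values without a block does not count the degrees of freedom it used. The planned fit had no block, and results with replicate number as a block (15 residual degrees of freedom) are given beside it.

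Further alternatives were quantile normalisation without background correction, the authors' values, no filter on dim probes, detection on all 24 arrays, the mean of a gene's probes, slide as a block, each slide alone, only the groups compared, leaving out each array, and, added later, slide with replicate block and the authors' values with replicate block. The fit was tested on simulated data with known changes added to 200 genes, where it recovered between 35.8% and 71.6% of 2-fold changes and between 3.30% and 9.28% of calls were wrong. Simulated genes and arrays were independent, without the shared variation by replicate number of the real arrays. These shares therefore need not hold for the real data. Between 17663 and 19830 probes were detected per array, correlations between arrays ran from 0.937 to 0.988, and 0 arrays were identical. For arrays, their number of 4 per group limits precision.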

Results

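Total RNA of C4-2B cells, an androgen-responsive human prostate cancer line of the LNCaP lineage, was measured on 24 single-colour Illumina bead arrays. Cells had received an siRNA against a non-specific sequence (siNS), against EP300 (sip300) or against CREBBP (siCBP). Each of the 3 arms was sampled without hormone and after 16 h with 10 nM dihydrotestosterone (DHT), a potent natural androgen. This gave 6 groups of 4 arrays. The sample titles say 0 h and 16 h of DHT and name neither a vehicle nor a common harvest time. Differences called DHT responses below may thus include other effects of those 16 h. EP300 encodes p300 and CREBBP encodes CBP, a pair of closely related histone acetyltransferases that act as coactivators of many transcription factors. The series title frames the question as whether both proteins serve androgen-regulated expression alike. Between 17663 and 19830 probes were detected per array, and 12438 genes were tested. Each slide carried 2 of the 4 arrays of every group, and the 2 slides differed in brightness, with mean raw signals of 782 ± 70.1 and 643 ± 43.7 (SD, n = 12 arrays). Changes below are log2 differences ± SE from a common limma fit with n = 4 arrays per group, with Benjamini-Hochberg adjusted 2-sided p-values, and a gene was called at an adjusted p under 0.05.

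Each siRNA lowered its own target. EP300 (probe ILMN_1744665) fell in sip300 cells by 0.88 ± 0.233 without DHT (adjusted p = 0.0181) and by 1.19 ± 0.233 with DHT (adjusted p = 0.00196), which left 54.3% and 43.9% of the siNS level. Without DHT the call ended when siNS replicate 3 (adjusted p = 0.0579) or sip300 replicate 1 (adjusted p = 0.0528) was left out. Its mean log2 signal was 8.16 ± 0.299 (SD, n = 4) in siNS and 7.28 ± 0.237 in sip300 without DHT, and 8.41 ± 0.337 and 7.22 ± 0.38 with DHT. In siCBP cells EP300 measured 8.58 ± 0.384 without and 8.35 ± 0.39 with DHT, neither called against siNS (adjusted p = 0.998 and 1.00). CREBBP (probe ILMN_1809583) fell in siCBP cells by 1.68 ± 0.189 without DHT (adjusted p = 0.000103) and by 1.74 ± 0.189 with DHT (adjusted p = 5.65e-05), which left 31.1% and 29.9%. CREBBP without DHT missed the threshold when only the groups compared were fitted. Its mean was 9.67 ± 0.214 and 9.48 ± 0.184 in siNS against 7.99 ± 0.362 and 7.74 ± 0.308 in siCBP, without and with DHT. A dim second CREBBP probe, with DHT undetected in both arms, differed by -0.40 without and 0.20 with DHT. In sip300 cells CREBBP measured 10.19 ± 0.28 and 9.95 ± 0.206, differences of 0.52 and 0.47 that were not called (adjusted p = 0.0818 and 0.104). With replicate number as a block they came close to the threshold (adjusted p = 0.0502 and 0.0710). Within slide 1 and slide 2 alone, with 2 arrays per group, EP300 differed by -0.99 and -0.78 without DHT and by -0.95 and -1.42 with DHT, and CREBBP by -1.97 and -1.39 and by -1.55 and -1.93. None of these within-slide differences was called, with adjusted p between 0.0560 and 0.779.

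**Figure D1:**
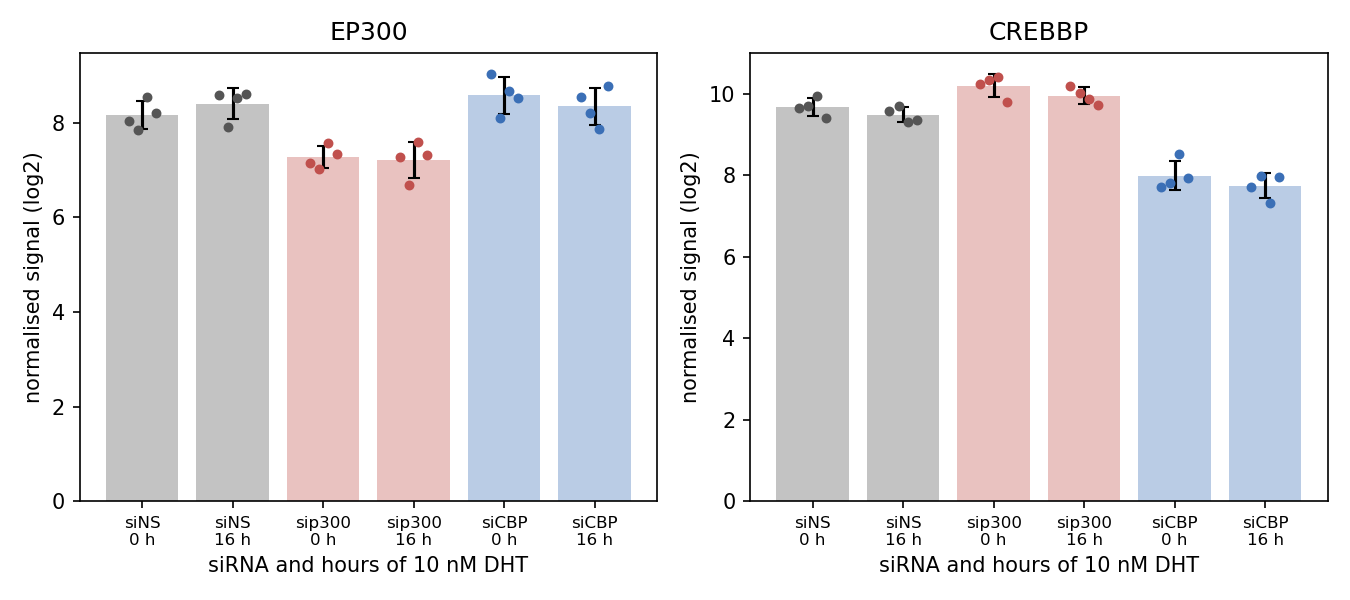
Normalised log2 signal (y axis) of EP300 (left) and CREBBP (right) on each of the 24 arrays, by siRNA and DHT time (x axis); points are single arrays, bars the group mean and whiskers 1 SD (n = 4). EP300 is lowest in the sip300 groups (means 7.28 and 7.22) and CREBBP in the siCBP groups (means 7.99 and 7.74).

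In cells with the control siRNA, DHT raised androgen-induced genes and lowered a smaller number of others. SGK1, a kinase induced by steroid hormones, rose by 4.80 ± 0.492 (adjusted p = 1.2e-06), the prostate transporter gene SLC45A3 by 4.10 ± 0.406, and KLK2, a prostate kallikrein protease, by 3.91 ± 0.437. NPPC, the precursor of C-type natriuretic peptide, rose by 3.79 ± 0.586 and RHOU, a small GTPase, by 3.61 ± 0.227 (adjusted p = 6.25e-10). SLC2A3, the glucose transporter GLUT3, was not detected on any array without DHT and was at least 5.43-fold higher with it (adjusted p = 5.65e-09). Such a bound raises each value of the undetected group to the lowest signal that passed detection on its array. PGC, which encodes pepsinogen C, ST6GALNAC1, a sialyltransferase, NBL1, an antagonist of bone morphogenetic proteins, and the transcriptional repressor gene ZBTB16 rose by 2.96 to 3.46. Among the genes that fell, SYTL2, a vesicle trafficking gene, dropped by 2.56 ± 0.384 and the homeobox genes HOXC9 and HOXC13 by 2.38 ± 0.255 and 1.90 ± 0.241. GASK1B fell by 2.54, the phosphatase gene PTPRR by 2.40, PLPPR1 by 2.06, DEPTOR, an inhibitor of mTOR, by 1.89, the transglutaminase gene TGM3 by 1.86 and the myosin kinase gene MYLK by 1.78. C1QTNF6 was at least 2.88-fold lower. Other passing probes of PTPRR, PLPPR1 and C1QTNF6 differed by 0.12, -0.34 and -0.21 (unadjusted limma p not under 0.05).

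Of 31 measured members of the list of androgen-induced genes, 25 rose and 0 fell in siNS cells (28 and 1 when adjusted over the list alone). FKBP5, a co-chaperone of steroid receptors, rose by 2.70 ± 0.154, TMPRSS2, a serine protease gene, by 2.41 ± 0.337, and PMEPA1 and the efflux pump gene ABCC4 by 2.08 and 2.16. KLK3, which encodes prostate-specific antigen, was higher by 2.06 ± 0.661 without passing the test (adjusted p = 0.116). It passed with replicate number as a block (adjusted p = 0.00134). The list as a whole stood above other genes (limma camera, adjusted p = 3.87e-63, and 1.04e-06 with an estimated correlation). Endoplasmic reticulum chaperone genes rose too, 5 of 19 with 0 falling (12 adjusted over the list alone), among them DNAJB9 by 1.39 ± 0.229 and DNAJC3 by 1.16 ± 0.258 (list adjusted p = 3.93e-13, and 0.00529 with an estimated correlation). In the polyamine list, 3 of 9 rose and 0 fell (3 adjusted over the list alone), namely ODC1, the rate-limiting enzyme of polyamine synthesis, by 1.52 ± 0.179, spermine synthase SMS by 1.01 ± 0.165 and SAT1, which acetylates and so breaks down polyamines, by 1.25 ± 0.23 (list adjusted p = 0.00155, and 0.0302 with an estimated correlation). Cholesterol and fatty acid synthesis genes shifted upward (median 0.27, adjusted p = 0.000243), with ACACA and ELOVL5 called among 26 (3 adjusted over the list alone). That list call was lost with an estimated correlation (adjusted p = 0.572 with an estimated correlation). Of 18 androgen-repressed genes, CDK8 and CAMK2N1 fell by 1.30 and 1.32 and LIFR rose by 1.24 (2 fell and 1 rose adjusted over the list alone). That list passed only with replicate number as a block (adjusted p = 0.167 without and 0.00690 with it).

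In all, 335 of 12438 genes changed with DHT in siNS cells, 216 higher and 119 lower. With replicate number as a block the same test called 737 genes, 409 higher and 328 lower, and the authors' processed values gave an even split of 675 higher and 666 lower. Within slides 1 and 2 alone, 67 and 64 genes were called.

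The response with siCBP closely resembled that with siNS. SLC45A3 rose by 4.17 ± 0.406, SGK1 by 4.13 ± 0.492, KLK2 by 3.64 ± 0.437, RHOU by 3.27 ± 0.227, ZBTB16 by 3.22 ± 0.382 and TMPRSS2 by 3.07 ± 0.337, with adjusted p between 3.11e-09 and 1.3e-05. FKBP5 rose by 2.65 ± 0.154, ST6GALNAC1 by 3.06, PGC by 2.90 and NBL1 by 2.79. SLC2A3 was again undetected without DHT and at least 3.03-fold higher with it. SYTL2, PTPRR, HOXC9 and MYLK fell by 2.26, 2.21, 2.14 and 1.87, as did the scavenger receptor gene COLEC12 by 2.04, the ubiquitin ligase genes LTN1 by 1.99 and MID1 by 1.97. CCDC83, the kinase gene MAP3K8 and C1QTNF6 were at least 2.71-fold, 2.21-fold and 2.43-fold lower. Other passing probes of PTPRR and C1QTNF6 differed by -0.23 and 0.12 (unadjusted limma p not under 0.05). KLK3 was higher by 2.22 ± 0.661 without passing the test (adjusted p = 0.0911, and 0.000716 with replicate number as a block). Of the androgen-induced list, 23 of 31 rose and 0 fell (28 adjusted over the list alone), and the list passed (adjusted p = 2.04e-71, and 5.86e-07 with an estimated correlation). Chaperone genes rose, 3 of 19 (8 adjusted over the list alone; list adjusted p = 2.31e-11, and 0.00962 with an estimated correlation), with DNAJB9 at 1.45 ± 0.229 and SDF2L1 at 0.63. Of the polyamine list, 3 of 9 rose (3 adjusted over the list alone; list adjusted p = 0.00133, and 0.0302 with an estimated correlation), ODC1 by 1.14 ± 0.179. The lipid synthesis list shifted upward (median 0.26, adjusted p = 4.91e-05) with SCAP and ACACA called (2 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.519 with an estimated correlation). The androgen-repressed list (median -0.49, adjusted p = 0.203 without and 0.00717 with the block) and the hypoxia and glycolysis list (median 0.11, adjusted p = 0.147 without and 0.00949 with the block) passed only with replicate number as a block.

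With siCBP, DHT changed 277 genes, 171 higher and 106 lower. With replicate number as a block 610 were called, 310 higher and 300 lower, and the authors' processed values gave 501 higher and 557 lower. Taken singly, slides 1 and 2 gave 38 and 64 called genes. Of the 171 that rose, 144 were also called higher in siNS cells, against 2.97 for independent lists, and of the 106 that fell 70 were shared, against 1.01. These arms share no array, but all comparisons use the same estimate of each gene's spread from the common fit. The numbers for independent lists, here and below, may therefore be too low.

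With sip300, 6 of the 10 genes named for the largest rises in siNS cells were also called. SGK1 rose by 4.48 ± 0.492, RHOU by 3.87 ± 0.227, ZBTB16 by 3.79 ± 0.382, C1orf116 by 3.73 ± 0.288 and SLC45A3 by 3.68 ± 0.406, with adjusted p between 2.85e-10 and 6.65e-06. KLK2 was undetected in sip300 cells without DHT and at least 7.2-fold higher with it (adjusted p = 0.00015). NPPC, SLC2A3, PGC and ST6GALNAC1, all undetected in sip300 cells without DHT, were not called (adjusted p = 0.999, 0.345, 0.0806 and 0.147; PGC and ST6GALNAC1 passed with replicate number as a block, adjusted p = 0.00363 and 0.00225). NBL1, PMEPA1, ABCC4 and the transcription factor gene AFF3 rose by 2.75, 2.56, 2.54 and 2.46, FKBP5 by 2.25 ± 0.154 and TMPRSS2 by 2.15 ± 0.337. KLK3 was higher by 2.45 ± 0.661 without passing the test (adjusted p = 0.117, and 0.000614 with replicate number as a block). Only 7 genes fell. They included the orphan nuclear receptor gene NR4A2 by 1.68 ± 0.269, the orphan receptor gene GPR63 by 1.19, the semaphorin gene SEMA6A by 1.03, the kinase anchoring gene AKAP7 by 0.95, NCOA7 by 0.85 and NDUFAF4, an assembly factor of respiratory complex I, by 0.73. NR4A2 was detected on 2 of 4 sip300 arrays with DHT, and another passing probe of it differed by -0.30 (unadjusted limma p not under 0.05). Of the androgen-induced list 19 of 31 rose and 0 fell (27 adjusted over the list alone; list adjusted p = 1.17e-90, and 1.7e-07 with an estimated correlation). Of 19 chaperone genes limma called 0 (1 adjusted over the list alone), yet the list shifted upward by a median of 0.25 (adjusted p = 3.72e-07, and 0.0420 with an estimated correlation). Of the polyamine list 2 of 9 rose, SMS by 0.86 and ODC1 by 0.91 (2 adjusted over the list alone; list adjusted p = 0.000298, and 0.0150 with an estimated correlation). The lipid synthesis list (median 0.15, adjusted p = 0.00123) and the cell cycle list (median -0.19, adjusted p = 0.00673) passed with no member called, and both calls were lost with an estimated correlation (adjusted p = 0.659 and 0.827 with an estimated correlation).

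With sip300, DHT changed 88 genes, 81 higher and 7 lower, fewer than in either other arm, and 674 had an unadjusted p under 0.05. The last number is close to what chance alone would give in 12438 tests, and was 1110 in the fit with the block. With replicate number as a block 205 were called, 156 higher and 49 lower, and the authors' processed values gave 248 higher and 131 lower. Within slides 1 and 2, 47 and 32 genes were called. Of the 81 that rose, 63 were also called higher in siNS cells, against 1.41 for independent lists, and 62 in siCBP cells, against 1.11. Of the 7 that fell, 1 was also called lower in siNS cells and 2 in siCBP cells (33 of 49 in each with replicate number as a block).

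Whether the DHT response itself differed between arms was tested gene by gene as a difference of differences. Only SLC2A3 was called between sip300 and siNS, lower with sip300 (adjusted p = 0.00109). It was undetected on all arrays without DHT in both arms, so no size of this difference is given. Levels below detection may also differ between arms, so a weaker response cannot be told apart from a lower level with sip300. SLC2A3 measured 5.54 ± 0.588 (SD, n = 4) with DHT in sip300 cells, where 2 of 4 arrays detected it, against 8.22 ± 0.541 in siNS and 7.41 ± 0.426 in siCBP cells. Its response was not called as different between siCBP and siNS (adjusted p = 1.00) or between sip300 and siCBP (adjusted p = 0.153). With replicate number as a block 11 genes differed between sip300 and siNS, 4 with a larger and 7 with a smaller value, and the authors' processed values gave 57, 23 larger and 34 smaller. Between siCBP and siNS limma called 0 genes (0 with replicate number as a block, 3 on the authors' processed values), with 196 at an unadjusted p under 0.05, and between sip300 and siCBP 0 genes (0 and 35), with 343. Both 196 and 343 are below the number that chance alone would give at that threshold in 12438 tests. With replicate number as a block they were 350 and 644. The fit without a block was thus conservative here, and 0 calls do not show equal responses. Called within slide 1 or slide 2 were 0 genes for each of these 3 contrasts. The chaperone list responded less with sip300 than with siNS (median difference -0.26, adjusted p = 0.000167) and than with siCBP (median -0.19, adjusted p = 0.00988), with no member called in either (limma, 0 adjusted over the list alone). Both calls were lost with an estimated correlation (adjusted p = 0.167 and 0.400 with an estimated correlation). The leukocyte marker list, of which 5 of 12 genes were measured, also passed between sip300 and siNS (median -0.45, adjusted p = 0.0227) with no member called. It was lost with an estimated correlation (adjusted p = 0.135 with an estimated correlation) and with replicate number as a block (adjusted p = 0.0600).

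As a score, the mean log2 of the androgen-induced list rose by 1.94 ± 0.115 (SE) in siNS, 1.84 ± 0.104 in sip300 and 1.93 ± 0.121 in siCBP cells, in 4 of 4 arrays each. Each gave p = 0.0286 in an exact 2-sided permutation test over 70 arrangements, the smallest the design allows, and 0.0490 after Benjamini-Hochberg adjustment over 12 such tests. The responses differed by -0.11 ± 0.155 between sip300 and siNS (exact permutation p = 0.765 over 4900 arrangements), by -0.01 ± 0.167 between siCBP and siNS (p = 0.944) and by -0.10 ± 0.16 between sip300 and siCBP (p = 0.807). These arrangements shuffle siRNA labels within each DHT time, so the lower level of the score with sip300 widens their spread. Both p-values for sip300 thus come from a weak test, and equal responses cannot be concluded from them. The level of the score was lower with sip300 than with siNS, by -0.56 ± 0.0812 without and -0.67 ± 0.132 with DHT (exact p = 0.0286 each, adjusted 0.0490). With siCBP it differed by 0.06 ± 0.117 and 0.05 ± 0.119 (exact p = 0.6 and 0.743). Within slides 1 and 2 the response was 1.98 and 1.91 in siNS, 1.93 and 1.75 in sip300, and 1.80 and 2.06 in siCBP cells. The share of the response retained was estimated by a slope through the origin over genes called in the arm not compared, so the 2 shares rest on different genes. Over 277 genes called with siCBP, the sip300 response was 63.8% ± 5.47 (jackknife SE) of the siNS response, with 271 of the same sign. For genes chosen on 2 of the 4 sip300 replicates and measured on the others, a choice that favours genes responding with sip300, the mean ratio of sip300 to siNS responses was 0.969 (SD 0.117 over 6 choices). Over 88 genes called with sip300, the siCBP response was 94.8% ± 6.32 of the siNS response, with 86 of the same sign.

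**Figure D2:**
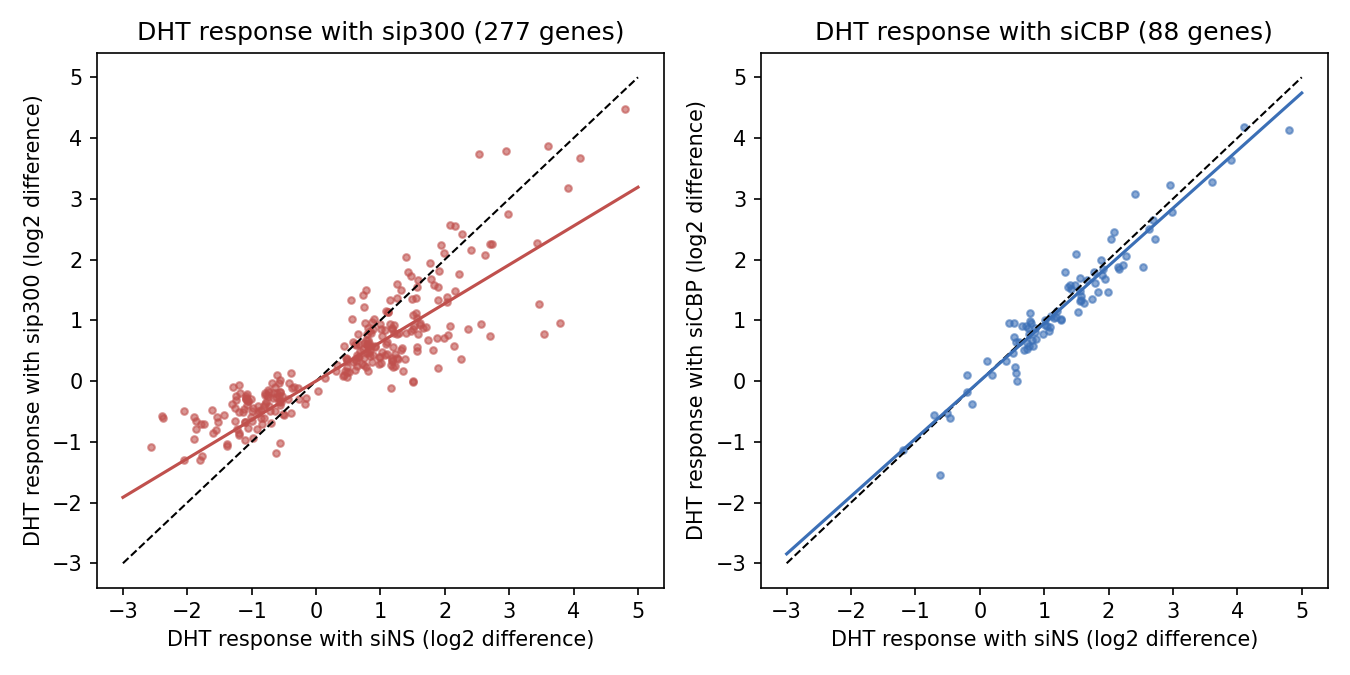
DHT response (log2 difference, 16 h minus 0 h) with sip300 (left, 277 genes called with siCBP) and with siCBP (right, 88 genes called with sip300) on the y axis against the response with siNS on the x axis; each point is a gene, the dashed line marks equal responses and the solid line is the slope through the origin. The slope is 63.8% for sip300 and 94.8% for siCBP, over different genes.

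Without DHT, sip300 raised IFIT1, IFIT2 and IFI6 and lowered KLK3 and TMPRSS2 among other genes. IFIT1 and IFIT2, which are induced by interferon and bind viral RNA, rose by 3.18 ± 0.688 (adjusted p = 0.00536) and 3.08 ± 0.718 (adjusted p = 0.00837), and IFI6 by 2.20 ± 0.479. FST, which encodes the activin antagonist follistatin, was undetected in siNS cells and at least 3.01-fold higher. PCDHB2, a protocadherin, NTNG1, an axon guidance gene, MAP2, a neuronal microtubule protein, LIX1L, RCAN2, a calcineurin regulator, and the metalloprotease gene ADAMTS1 rose by 2.05 to 2.20. The largest falls were in HTR3A, a serotonin receptor subunit, by 3.13 ± 0.313 (adjusted p = 5.88e-06), COLEC12 by 3.11 ± 0.471 and RPRML by 2.86 ± 0.283. C9orf152, the stress-induced cytokine gene GDF15, CYP1A2, GASK1B, TGM3, the growth factor gene BMP7 and PTPRR fell by between 2.30 and 2.71. Other passing probes of IFIT1 and PTPRR differed by 0.44 and -0.09 (unadjusted limma p not under 0.05). KLK3 fell by 2.51 ± 0.661 (adjusted p = 0.0178) and TMPRSS2 by 1.89 ± 0.337 (adjusted p = 0.00145). KLK2, undetected in sip300 cells, was at least 1.87-fold lower without passing the test (adjusted p = 0.0759, and 0.00895 with replicate number as a block), and FKBP5 was not called (higher by 0.13, adjusted p = 0.656).

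By list, 8 of 31 androgen-induced genes fell and 0 rose with sip300 in the absence of DHT (11 adjusted over the list alone), among them KLK4 by 1.46 and ABCC4 by 1.13 (list adjusted p = 4.1e-06, but adjusted p = 0.135 with an estimated correlation). Of the cell cycle list 5 of 39 fell and 0 rose (9 adjusted over the list alone), including the centromere gene CENPA by 1.08 and thymidine kinase TK1 by 0.94 (list adjusted p = 5.13e-09, but adjusted p = 0.5 with an estimated correlation). Of the ATF4 and amino acid response list 7 of 22 fell and 0 rose (11 adjusted over the list alone), led by the amino acid transporter gene SLC7A5 by 2.03 ± 0.237 (list adjusted p = 1.03e-07, but adjusted p = 0.318 with an estimated correlation). Of the interferon list 7 of 23 rose and 0 fell (8 adjusted over the list alone), among them IRF9, a subunit of the interferon-activated factor, by 1.43 ± 0.27 (list adjusted p = 0.000298, but adjusted p = 0.569 with an estimated correlation). The hypoxia and glycolysis list was lower (median -0.53, adjusted p = 0.0272), with 0 of 22 falling and 1, the vasodilator peptide gene ADM, rising by 1.74 (1 adjusted over the list alone). The lipid synthesis list was lower too (median -0.25, adjusted p = 0.0298), with INSIG1 the 1 member that fell among 26 (1 adjusted over the list alone). Both were lost with an estimated correlation (adjusted p = 0.827 and 0.798 with an estimated correlation). In the list of acetyltransferases and receptor coregulators KAT2B, another acetyltransferase, and NCOA1, a steroid receptor coactivator, rose by 1.10 and 0.60 and EP300 fell (2 rose and 1 fell adjusted over the list alone). The list passed with a median of 0.29 (adjusted p = 0.0427), but not with replicate number as a block (adjusted p = 0.0600) or with an estimated correlation (adjusted p = 0.319 with an estimated correlation).

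A total of 1240 genes changed with sip300 without DHT, 689 higher and 551 lower, and 2602 were called with replicate number as a block, 1446 higher and 1156 lower. Within slides 1 and 2, 44 and 172 genes were called, and leaving out siNS replicate 1 without DHT gave 690.

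With DHT, sip300 again raised IFIT1, IFIT2 and IFI6 and lowered KLK3 and TMPRSS2. CBLN2, a secreted synaptic organiser, rose by 4.06 ± 0.851 (adjusted p = 0.00312), IFIT1 by 3.95 ± 0.688, IFIT2 by 3.31 ± 0.718, PCDHB2 by 2.54 ± 0.325 and IFI6 by 2.52 ± 0.479. Another passing IFIT1 probe differed by 0.22 (unadjusted limma p not under 0.05). The metalloprotease gene MMP16, NTNG1, MAP1B, a neuronal microtubule protein, and LIX1L rose by 2.23 to 2.41, and RCAN2, undetected in siNS cells, was at least 3.44-fold higher. NPPC fell by 3.49 ± 0.586 (adjusted p = 0.000578), CYP1A2 by 3.31 ± 0.729, RPRML by 2.87 ± 0.283, GDF15 by 2.80 ± 0.659, SLC2A3 by 2.69 ± 0.253 and HTR3A by 2.64 ± 0.313. C9orf152, PGC and PHLDA2, an imprinted growth regulator, fell by 2.43 to 2.44, and COLEC12 was at least 4.02-fold lower. TMPRSS2 fell by 2.15 ± 0.337 (adjusted p = 0.000287), KLK3 by 2.12 ± 0.661 (adjusted p = 0.0344) and KLK2 by 1.96 ± 0.437 (adjusted p = 0.00475), whereas FKBP5 differed by -0.32 ± 0.154 (adjusted p = 0.177).

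**Figure D3:**
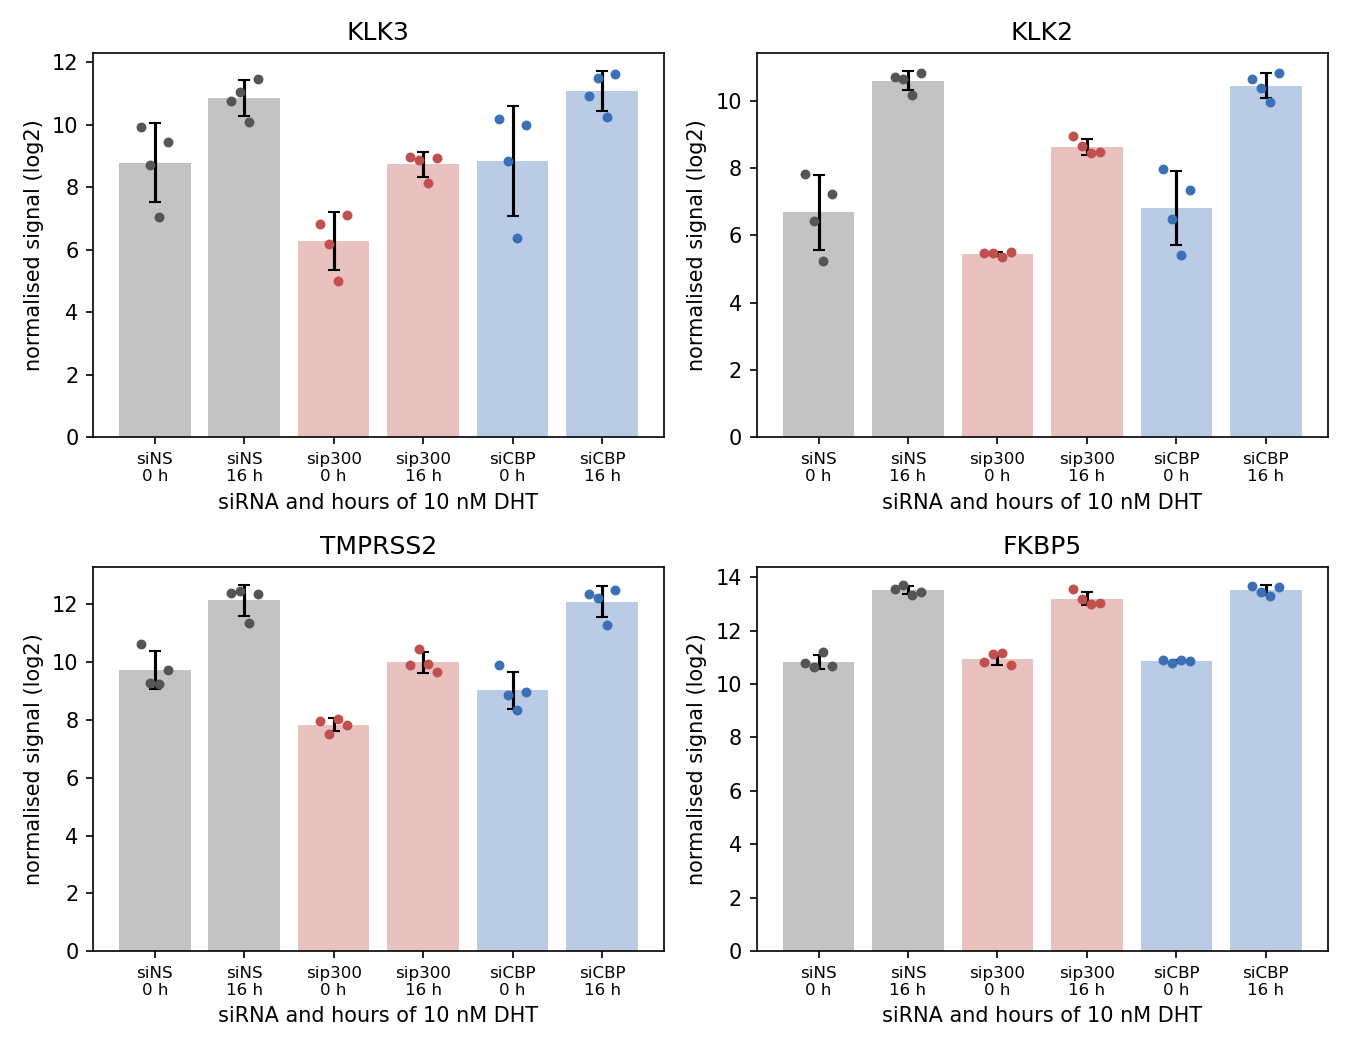
Normalised log2 signal (y axis) of KLK3, KLK2, TMPRSS2 and FKBP5 on each array, by siRNA and DHT time (x axis); points are arrays, bars group means and whiskers 1 SD (n = 4). KLK3 has means of 6.27 and 8.73 in sip300 cells without and with DHT, against 8.78 and 10.84 in siNS cells.

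Of the androgen-induced list 12 of 31 fell and 0 rose with sip300 under DHT (14 fell adjusted over the list alone). TRPM8, a cold-sensing ion channel, fell by 1.70 ± 0.238, the methyltransferase gene GNMT by 1.32 ± 0.234, and the acute-phase gene ORM1 was at least 2.67-fold lower (list adjusted p = 4.69e-07, but adjusted p = 0.0995 with an estimated correlation). Of the cell cycle list 16 of 39 fell and 0 rose (20 adjusted over the list alone), including PCNA, the replication clamp, by 0.88 ± 0.171 and CENPA by 1.01, with CDC6 at least 1.4-fold lower (list adjusted p = 9.85e-12, but adjusted p = 0.400 with an estimated correlation). Of the ATF4 and amino acid list 8 of 22 fell (12 adjusted over the list alone), SLC7A5 by 1.79 ± 0.237, MTHFD2 by 0.75 and the secreted glycoprotein gene STC2 by 1.40 (list adjusted p = 6.81e-06, but adjusted p = 0.400 with an estimated correlation). Of the interferon list 9 of 23 rose and 0 fell (9 adjusted over the list alone), among them RIGI, a sensor of viral RNA, by 1.31 ± 0.25 (list adjusted p = 5.25e-05, but adjusted p = 0.515 with an estimated correlation). Of the chaperone list 5 of 19 fell (9 adjusted over the list alone), with SDF2L1, DNAJC3 and PDIA4 falling by 0.71, 1.02 and 0.69 (list adjusted p = 0.000112, but adjusted p = 0.155 with an estimated correlation). Of the hypoxia and glycolysis list 3 of 22 fell (3 adjusted over the list alone), namely ANKRD37 by 1.81, the glucose transporter gene SLC2A1 by 1.17 and hexokinase HK2 by 1.29 (list adjusted p = 0.00722, but adjusted p = 0.762 with an estimated correlation). Of the lipid synthesis list 4 of 26 fell (4 adjusted over the list alone), including fatty acid synthase FASN by 0.68 (list adjusted p = 0.00265, but adjusted p = 0.678 with an estimated correlation). NCOA1, KAT2B and HDAC3 rose by 0.96, 0.73 and 0.44 and EP300 fell among 20 coregulators (7 rose and 2 fell adjusted over the list alone; list adjusted p = 0.0402, but adjusted p = 0.318 with an estimated correlation). Of 12 luminal prostate markers SPDEF, a prostate transcription factor, AZGP1, keratin KRT19 and KLK3 fell (4 adjusted over the list alone), the first by 1.28 ± 0.229 (list adjusted p = 0.0399, but adjusted p = 0.265 with an estimated correlation).

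Lists that did not pass in this comparison still had single called members. Among p53 targets (median 0.07, adjusted p = 0.983) TP53I3 rose by 1.85 while CDKN1A, a cyclin-dependent kinase inhibitor, and GDF15 fell by 0.83 and 2.80. Among NF-kB targets (median 0.15, adjusted p = 0.685) the interferon regulatory factor gene IRF1 was at least 2.37-fold higher, and among CREB and immediate early genes (median -0.28, adjusted p = 0.454) the neuropeptide precursor gene VGF fell by 1.62. For androgen-repressed genes the median was 0.44 (adjusted p = 0.785), with AKR1C3 at least 1.06-fold higher and CAMK2N1 and PRUNE2 lower by -1.65 and -0.97. As markers of other cell types, basal epithelium (median 0.32, adjusted p = 0.592, 2 genes), stroma (median -0.19, adjusted p = 0.949, 7 genes), leukocytes (median -0.25, adjusted p = 0.231, 5 genes) and neuroendocrine cells (median 0.96, adjusted p = 0.288, 3 genes) did not pass. TUBB3, a neuronal tubulin listed for the last of these, rose by 1.99 ± 0.551, the smooth muscle actin gene ACTA2 of the stroma list by 1.51 ± 0.354, and the actin-binding leukocyte gene CORO1A fell by 0.80. The polyamine list (median -0.29, adjusted p = 0.167) had ODC1 and SRM lower by -0.78 and -0.73 and AZIN1 higher by 0.41.

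With DHT, 1815 genes changed with sip300, 1018 higher and 797 lower, and 3100 with replicate number as a block, 1730 higher and 1370 lower. Within slides 1 and 2, 428 and 40 genes were called, and leaving out sip300 replicate 1 with DHT gave 1086. Of the 1018 that rose, 476 had also risen without DHT, against 56.4 for independent lists, and of the 797 that fell 362, against 35.3. These comparisons share no array, but they share the estimate of each gene's spread. Genes that responded to DHT in siCBP cells were also followed, though their choice was not independent of the other arms. Their DHT differences compare siCBP arrays only, but the spread used to call them came from the common fit to all groups. These genes may thus have a smaller estimated spread than all genes, which would favour calls with sip300 as well. Of 171 induced ones, 78 fell and 2 rose with sip300 under DHT, 45.6% against 6.41% of all genes (list adjusted p = 1.32e-24, and 0.00185 with an estimated correlation). Without DHT 26 fell and 7 rose, 15.2% lower against 4.43% of all genes (list adjusted p = 8.34e-05, but 0.226 with an estimated correlation). Of 106 genes lowered by DHT, 31 fell and 7 rose with sip300 without DHT, 29.2% lower against 4.43% of all genes (adjusted p = 2.21e-07, and 0.0203 with an estimated correlation). With DHT 7 fell and 23 rose, 21.7% higher against 8.18% of all genes (adjusted p = 0.0627, and 0.389 with an estimated correlation).

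**Figure D4:**
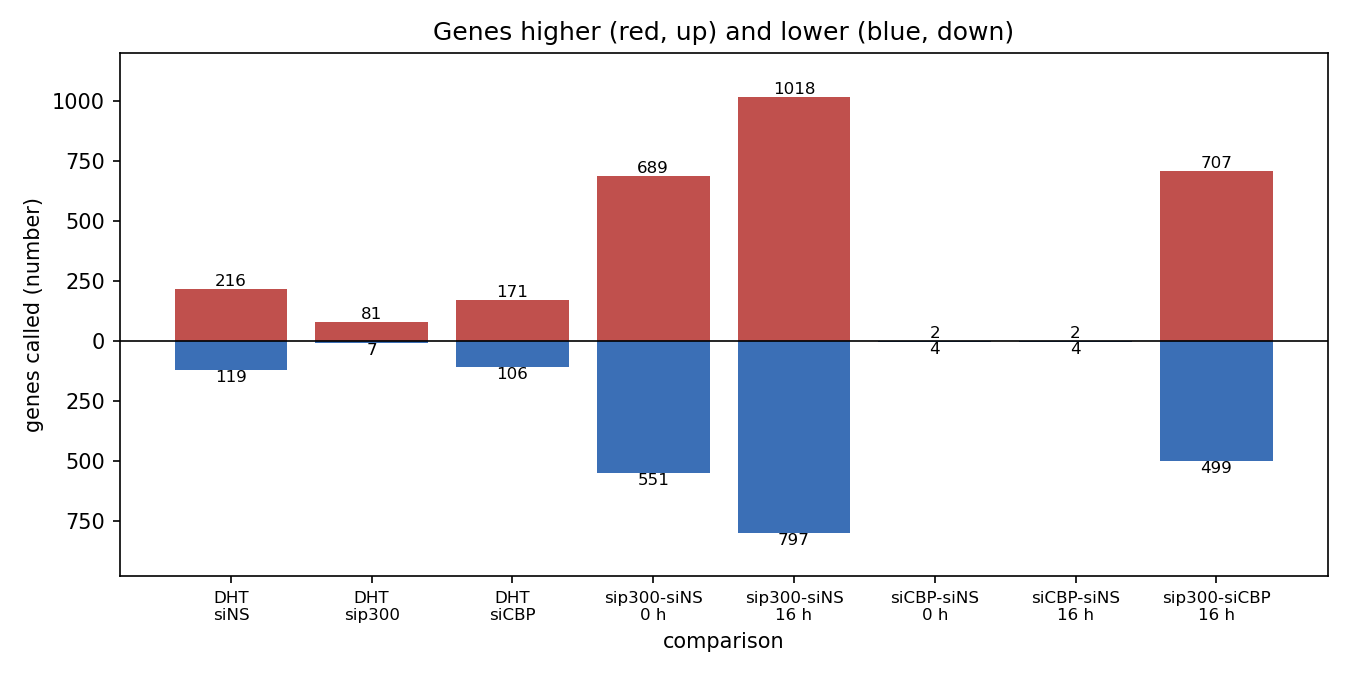
Number of genes called (y axis) in each comparison (x axis), with genes that rose above and genes that fell below the zero line. The sip300 comparisons hold 1240 and 1815 called genes without and with DHT, and the siCBP comparisons 6 and 6.

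With siCBP very few genes changed. Besides CREBBP, the channel gene PANX2 fell by 1.08 ± 0.166 without DHT (adjusted p = 0.00544) and by 0.97 ± 0.166 with DHT (adjusted p = 0.0190), the stress kinase gene MAPK9 by 0.98 and 0.94, and SCO1, a copper chaperone for cytochrome c oxidase, by 0.94 and 0.83. The non-coding RNA LINC00161 rose by 1.92 ± 0.346 without DHT (adjusted p = 0.0266), and so did LTN1, named after its values were seen, by 1.47 ± 0.26 (adjusted p = 0.0265). With DHT ANXA9, an annexin, and PNMA1 rose by 1.07 ± 0.166 and 1.02 ± 0.19. KLK3 differed from siNS by 0.07 and 0.23, KLK2 by 0.12 and -0.14, TMPRSS2 by -0.70 and -0.04 and FKBP5 by 0.04 and -0.01, without and with DHT, and none was called (adjusted p between 0.998 and 1.00).

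Of the androgen-induced list 0 of 31 genes were called with siCBP at either time (limma, 0 adjusted over the list alone), and the list did not pass with DHT (median 0.06, adjusted p = 0.454). Of all genes, 582 and 584 had an unadjusted limma p under 0.05 without and with DHT, below the number that chance alone would give in 12438 tests. With replicate number as a block these counts were 1059 and 1074. The cell cycle list was lower by medians of -0.23 without DHT (adjusted p = 1.66e-06) and -0.27 with DHT (adjusted p = 6.28e-08), with 0 of 39 called (0 adjusted over the list alone); both calls were lost with an estimated correlation (adjusted p = 0.608 and 0.521 with an estimated correlation). The chaperone list was higher without DHT (median 0.13, adjusted p = 0.00429) with 0 of 19 called, and lost with an estimated correlation (adjusted p = 0.358 with an estimated correlation). The androgen-repressed list passed only with replicate number as a block, in the upward direction (median 0.22 and 0.24, adjusted p = 0.321 and 0.230 without, 0.0353 and 0.0138 with the block). The interferon list did not pass with DHT (median -0.01, adjusted p = 0.381). Of 81 genes induced by DHT in sip300 cells, 0 fell and 0 rose with siCBP at either time. Of all genes 0.0322% fell and 0.0161% rose each time, so so few calls could hardly include any of the 81.

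With siCBP 6 genes were called without DHT and 6 with DHT, 2 higher and 4 lower each time, and the 4 lower genes, the siRNA target CREBBP among them, were the same, against 0.00129 for independent lists. With replicate number as a block 16 and 23 were called, 4 and 8 higher and 12 and 15 lower, and the authors' processed values gave 49 higher and 57 lower, and 63 higher and 80 lower. Within either slide 0 genes were called, and single arrays left out gave between 2 and 7 and between 1 and 5 genes. Fitting only the groups compared gave 0 genes without and 1 with DHT.

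A direct comparison of sip300 with siCBP cells under DHT reused the 4 sip300 arrays above. CBLN2, IFIT1, IFIT2 and PCDHB2 were higher with sip300 by 3.95 ± 0.851, 3.83 ± 0.688, 3.12 ± 0.718 and 3.11 ± 0.325 (adjusted p between 6.78e-06 and 0.00842), as were IFI44 by 2.58, TUBB3 by 2.37 and the non-coding RNA gene HCP5 by 2.29. The other passing IFIT1 probe differed by 0.22 (unadjusted limma p not under 0.05). NTNG1 and RCAN2, undetected in siCBP cells, were at least 5.01-fold and 3.4-fold higher, and CREBBP was higher by 2.21 ± 0.189. GDF15 was lower by -3.39 ± 0.659, CYP1A2 by -2.58, CAMK2N1 by -2.47, C9orf152 by -2.42, RPRML by -2.35 and the retinaldehyde dehydrogenase gene ALDH1A3 by -2.24 ± 0.232. The near-identical tubulin genes TUBA3C and TUBA3E, whose probes were not told apart here, were lower by -2.41 and -2.12, and S100P was at least 3.27-fold lower. KLK3, TMPRSS2 and KLK2 were lower by -2.34 ± 0.661, -2.11 ± 0.337 and -1.82 ± 0.437, EP300 by -1.13 ± 0.233, and FKBP5 differed by -0.31 (adjusted p = 0.216).

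Of the androgen-induced list 12 of 31 were lower and 0 higher with sip300 than with siCBP (15 lower adjusted over the list alone), among them ORM1, at least 3.18-fold (list adjusted p = 8.89e-10, and 0.0329 with an estimated correlation). Of the chaperone list 8 of 19 were lower (8 adjusted over the list alone), DNAJB9 by -1.03 ± 0.229 and XBP1, the transcription factor of the unfolded protein response, by -0.86 ± 0.216 (list adjusted p = 3.34e-07, and 0.0420 with an estimated correlation). The remaining lists that passed were lost with an estimated correlation. They were interferon (10 of 23 higher, 10 adjusted over the list alone; adjusted p = 2.39e-07, and 0.358 with an estimated correlation), ATF4 and amino acids (6 of 22 lower, 8 adjusted over the list alone; 1.39e-06, and 0.358), cell cycle (2 of 39 lower, 0 adjusted over the list alone; 1.76e-05, and 0.661), lipid synthesis (1 of 26 lower, 0 adjusted over the list alone; 0.01, and 0.739), luminal prostate (3 of 12 lower, 6 adjusted over the list alone; 0.0119, and 0.135), hypoxia and glycolysis (1 of 22 lower, 1 adjusted over the list alone; 0.0169, and 0.824) and coregulators (2 of 20 higher and 1 lower, 4 and 1 adjusted over the list alone; 0.0329, and 0.303). A total of 1206 genes differed, 707 higher and 499 lower with sip300, and 2408 with replicate number as a block. Slides 1 and 2 singly gave 183 and 17 called genes, and leaving out sip300 replicate 1 with DHT gave 666.

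**Figure D5:**
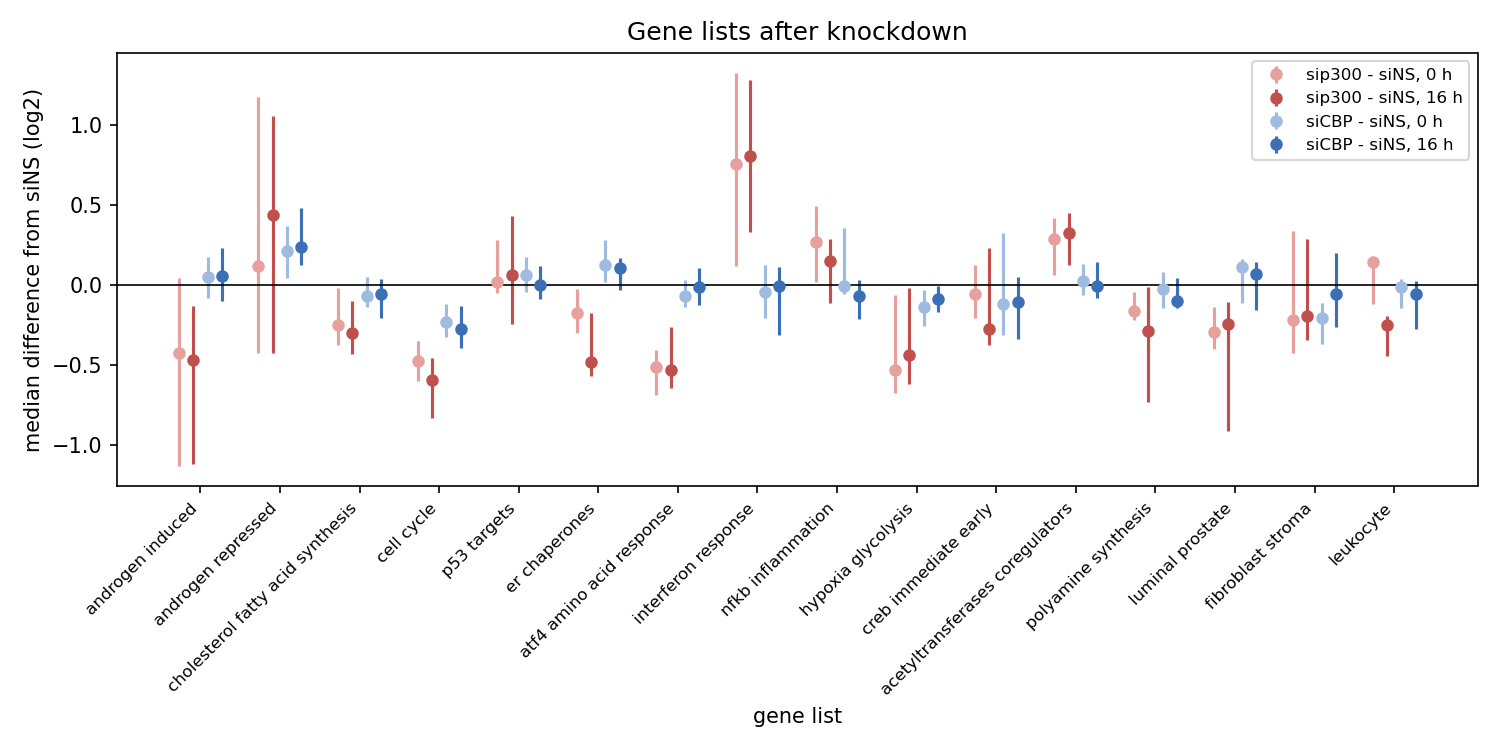
Median log2 difference from siNS (y axis) of each of the fixed gene lists of at least 5 measured genes (x axis), for sip300 and siCBP without and with DHT; whiskers span the quartiles of the list's genes. The interferon list has medians of 0.76 and 0.81 with sip300 and -0.01 with siCBP under DHT, and the cell cycle list -0.48 and -0.59 with sip300 and -0.23 and -0.27 with siCBP.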

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

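Of the tests in this part, the siCBP comparison of the interferon list, the estimated correlation for the cell cycle list, the splits scored for shared genes, the swaps within a replicate number and the splits of responses were chosen only after the result was seen.

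A DHT response that differed between siRNA arms was called for SLC2A3, lower with sip300 than with siNS (fitted log2 value -2.77, limma, adjusted p = 0.00109). It was detected on 0 of 4 arrays of both arms without DHT, and with DHT on 4 of 4 siNS and 2 of 4 sip300 arrays, so the fitted value is not a measured size. Levels below detection may differ between arms, so a weaker response cannot be told apart from a lower level with sip300 at both times. As lists, endoplasmic reticulum chaperones responded less with sip300 than with siNS (median -0.26) and than with siCBP (median -0.19), and the 5 measured leukocyte markers less than with siNS (median -0.45). With an estimated correlation none of these 3 list results passed (adjusted p between 0.135 and 0.400). Among probes without a gene symbol, which the gene comparisons leave out, limma called 69 of 6379 for DHT in siNS cells and 164 for sip300 with DHT.

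In 24 of 548 sets of 4 arrays 1 array stood far from the other 3, where chance alone gives about 1 in 20, or 27.4. The number given is the gap to the nearest array over the whole range. With siNS and DHT these were CENPA (0.873, replicate 1 higher), EP300 (0.895, replicate 2 lower), HLA-E (0.907, replicate 3 lower), PHLDA2 (0.918, replicate 3 lower), PLPPR1 (0.833, replicate 3 lower), SLC7A5 (0.864, replicate 1 lower), TMPRSS2 (0.909, replicate 3 lower) and the neuroendocrine list (0.960, replicate 2 higher). With siNS alone they were DNAJB9 (0.853, replicate 3 lower), LTN1 (0.954, replicate 3 higher), MAPK9 (0.833, replicate 2 lower), the lipid synthesis list (0.856, replicate 2 lower) and the NF-kB list (0.892, replicate 2 lower). With sip300 alone they were MAP2 (0.831, replicate 4 higher), ODC1 (0.860, replicate 1 lower), PCDHB2 (0.830, replicate 4 lower) and SMS (0.853, replicate 1 lower). With sip300 and DHT they were HOXC9 (0.866, replicate 2 lower), KLK3 (0.868, replicate 3 lower), KRT19 (0.857, replicate 4 higher), SPDEF (0.857, replicate 4 lower) and ZBTB16 (0.840, replicate 2 lower). With siCBP alone they were HOXC9 (0.830, replicate 4 higher) and the coregulator list (0.900, replicate 3 higher).

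The interferon list was higher with sip300 by medians of 0.76 and 0.81 without and with DHT. A response to any siRNA is argued against by siCBP, whose median difference with DHT was -0.00613, though the control was itself an siRNA. An origin in 1 replicate number is argued against by the lowest of 8 differences within a number, 0.229, though numbers 1 and 3 (1.84 and 1.03 without, 1.90 and 1.54 with DHT) exceeded 2 and 4 (0.60 and 0.23, 0.55 and 0.28). The exact permutation p of the list's mean was 0.0571 without and 0.0286 with DHT (differences 0.92 and 1.07, higher in 4 of 4 numbers). An exact sign-flip permutation test within replicate numbers gave p = 0.125 at both times, the smallest that 4 pairs allow. However, 12 of 35 splits of the 8 arrays with DHT gave as small a list p (lowest other 2.44e-14). Chance could thus not be excluded by these splits. An effect of this EP300 siRNA other than the loss of p300 cannot be told apart, since the labels name 1 kind of siRNA against EP300. The list call was lost with an estimated correlation (adjusted p = 0.569 without and 0.515 with DHT), so no increase beyond that of other genes is established.

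The DHT response was weaker with sip300 over genes chosen with siCBP, at 63.8% of the siNS response. A larger spread between sip300 arrays was checked by the ratio of median SDs, which was 1.03. Random noise in the sip300 responses would not by itself lower this slope, so the ratio cannot decide on this pattern. Compression near the background is argued against as the whole explanation by the bright genes, whose slope was 0.772 ± 0.0719 (jackknife SE), against 0.571 ± 0.0541 for the 161 dimmer of the 277 genes. The choice of genes stays open: genes chosen on 2 of the 4 replicates of the sip300 arm and measured on the other 2 had a mean ratio of sip300 to siNS responses of 0.969 (SD 0.117 over 6 choices), against 0.672 (SD 0.0808) for genes chosen in siCBP. Choosing genes for their response with sip300 itself favours genes that kept it, so this ratio does not settle what the choice of genes contributed.

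The cell cycle list was lower with siCBP by medians of -0.23 and -0.27. An origin in 1 replicate number is argued against by the highest of 8 differences within a number, -0.14, with 4 of 4 numbers lower at both times, and 1 of 35 splits, the real one, gave as small a list p (lowest other 4.28e-08). The exact permutation p of the list's mean, which ignores replicate number, was 0.371 without and 0.0286 with DHT. Without DHT the differences within a number ran from -0.33 to -0.15. Spread between numbers enters that permutation, so 0.371 does not show the absence of a decrease. An exact sign-flip permutation test within replicate numbers gave p = 0.125 at both times, the smallest that 4 pairs allow. Correlation between the list's genes stays open, as the adjusted p with an estimated correlation was 0.521 with DHT, so no decrease beyond that of other genes is established.

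Splitting the 8 arrays of each comparison in all 35 ways showed whether chance could give as many called genes. For DHT in siNS cells 1 split, the real one with 335 genes, called as many (highest other 15). The same held for DHT in siCBP cells (1 split, 277 genes, highest other 14), sip300 without DHT (1 split, 1240 genes, highest other 8), sip300 with DHT (1 split, 1815 genes, highest other 1), siCBP with DHT (1 split, 6 genes, highest other 3) and sip300 against siCBP (1 split, 1206 genes, highest other 3). By this count chance was not excluded for DHT in sip300 cells (2 splits, 88 genes, highest other 115) or for siCBP without DHT (2 splits, 6 genes, highest other 215). In both, the split with more genes set replicates 1 and 4 against 2 and 3, a structure of the samples by replicate number. Among the 8 splits that part all 4 pairs of equal number, the highest other count was 0 in these 2 comparisons and at most 3 in all 8. For the genes also called on other arrays chance is argued against: 1 of 35 splits, the real one, shared as many called genes for DHT in sip300 and siNS cells (64, highest other 1), for DHT in sip300 and siCBP cells (64, highest other 1) and for siCBP without and with DHT (4, highest other 0). The 4 shared with siCBP include CREBBP, the target of the siRNA itself. For the 3 differences of DHT responses 100 random splits were drawn. For sip300 against siNS 8 called at least 1 gene (highest other 262), so chance was not excluded by this count, but these splits also mix replicate numbers and the arms' differences without DHT. Swapping arms only within a replicate number still mixes the arms (19 of 100, highest other 2282). Splitting the 8 responses within a replicate number in all 35 ways removes differences in level between arms and between numbers. Such splits can still set the responses of some numbers against those of others. Here 2 splits called as many genes (7 genes, highest other 61), so chance was not excluded for this count either. For SLC2A3 alone, picked because it was called, 1 of these 35 splits, the real one, gave as small a p (adjusted p = 0.00879). For siCBP against siNS and sip300 against siCBP 0 genes were found, so any split calls as many (100 of 100 each, highest other 172 and 82) and this count tested nothing. On responses within a number, 0 and 1 genes were found there, and for the latter 3 of 35 splits called as many (highest other 1).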

How the results depend on the processing

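Of these settings, slide with replicate block together and the authors' values with replicate block were chosen after the data had been seen. Results are named in this order where counts are listed: DHT in siNS, sip300 and siCBP cells, sip300 without and with DHT, siCBP without and with DHT, sip300 against siCBP with DHT, and the difference of DHT responses between sip300 and siNS. No called gene named in the texts changed sign under the settings scored for it, which leave out the combined settings and, for genes that fail it, detection on all 24 arrays. With slide or replicate number as a block, or only the groups compared, fitted differences equal those of the planned fit in this balanced design, so no sign could change there. For lists that passed, the direction with an estimated correlation and with fry was taken from the planned fit, so a change of sign could not show. With slide or replicate number as a block no list that passed changed sign, but the fitted differences of genes stay the same there. The direction of genes not called was not scored. With replicate block the counts were 737, 205, 610, 2602, 3100, 16, 23, 2408 and 11, and all genes called without it were also called with it. With slide and replicate block together they were 869, 233, 715, 3022, 3535, 22, 34, 2815 and 15, with 11 for the difference between sip300 and siCBP. The authors' values gave 1341, 379, 1058, 3817, 4227, 106, 143, 3578 and 57, with 3 and 35 for the differences of siCBP from siNS and of sip300 from siCBP, and a retained share of 0.583 for sip300. With replicate block they gave 1063, 299, 856, 3333, 3778, 59, 70, 3075 and 35, with 1 and 15 for those differences. Blocking removes variation by replicate number, which accounted for 25.8% of the variation. Within slide 1 the counts were 67, 47, 38, 44, 428, 0, 0, 183 and 0, and within slide 2 they were 64, 32, 64, 172, 40, 0, 0, 17 and 0, with 2 arrays per group and so fewer residual degrees of freedom. Within a slide, DHT comparisons in siNS and sip300 cells held no replicate number in common, siCBP against siNS with DHT held the same numbers, and the others shared 1 of 2. There EP300 differed with sip300 by -0.99 and -0.78 without and -0.95 and -1.42 with DHT, CREBBP with siCBP by -1.97 and -1.39 and by -1.55 and -1.93, none called, and the retained share for siCBP was 0.862 within slide 1. Fitting only the groups compared, with fewer arrays, gave 219, 48, 169, 545, 1431, 0, 1 and 734 for the first 8, and CREBBP without DHT missed the threshold at -1.68 (adjusted p = 0.101). Over its other settings that adjusted p ranged up to 0.779 within slide 2. Quantile normalisation without background correction gave 3 genes for the difference between sip300 and siNS, and list responses of 1.5, 1.38 and 1.47 in siNS, sip300 and siCBP cells, as it leaves background in the signal. Detection on all 24 arrays, which tests fewer genes, gave 0 for that difference and a retained share of 0.708 for sip300, and slide as a block gave 2. Of 44 list results that passed, 11 passed with an estimated correlation, 25 with fry, 44 with slide as a block and 42 with replicate block. Over all list tests 30 passed with fry and 47 with replicate block. For causes not stated here, the cause was not tested.

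Leaving out 1 array at a time gave 690 (without siNS replicate 1) to 1299 genes for sip300 without DHT, with 771 without siNS replicate 4 and 789 without sip300 replicate 1. It gave 1086 (without sip300 replicate 1) to 1720 for sip300 with DHT, with 1132 and 1136 without siNS replicates 1 and 4, and 666 (without sip300 replicate 1) to 1246 for sip300 against siCBP, with 791 without sip300 replicate 3 and 766 and 701 without siCBP replicates 1 and 4. For siCBP it gave 2 (without siCBP replicate 1) to 7 without DHT, with 3 without siNS replicate 4 or siCBP replicate 3. With DHT it gave 1 (without siCBP replicate 1 or 3) to 5, with 3 without siNS replicate 1 or 2 or siCBP replicate 4 and 2 without siNS replicate 4. The difference between sip300 and siNS ranged from 1 to 5 (without siNS replicate 3 with DHT), with 2 without siNS replicate 4 with DHT or sip300 replicate 4 without, and that between sip300 and siCBP from 0 to 1 (without siCBP replicate 4 with DHT). EP300 with sip300 without DHT ranged from -0.98 to -0.75 and lost its call without siNS replicate 3 (adjusted p = 0.0579) or sip300 replicate 1 (adjusted p = 0.0528). DHT counts stayed within 1.5 times.

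Of 268 named gene results, 260 stayed on the same side of the threshold under replicate block and 8 became called, KLK3 under DHT in all 3 arms among them. Without a filter 10 lost it, with the mean of probes 9 lost and 1 gained it, without background correction 4 lost and 3 gained it, with the authors' values 13 gained it, and with slide as a block 1, MYLK in siNS cells, lost it. With only the groups compared 39 lost and 4 gained it, and within slides 1 and 2 alone 137 and 169 lost and 1 and 0 gained it. Leaving out an array ended a call for 62 of them and gave one to 5 at least once. Signal over background and 4 arrays per group limit small changes. On simulated data with independent genes and arrays, between 0% and 19.4% of changes of 0.5 in log2 were recovered, and between 81.8% and 100% of changes of 2.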

Other observations

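The genes in this paragraph and the next were chosen after their values were seen, and no test of them as groups was run. FST, which encodes the activin-binding protein follistatin, was undetected in siNS cells at both times. With sip300 it was at least 3.01-fold higher without DHT (adjusted p = 0.000278), and with DHT it was detected on 2 of 4 sip300 arrays (adjusted p = 0.00829). BMPR2, a bone morphogenetic protein receptor gene, rose with sip300 by 0.77 ± 0.199 and 0.97 ± 0.199 (adjusted p = 0.0164 and 0.00278). The ligand genes BMP7 and INHBB fell by 2.33 ± 0.339 and 0.97 ± 0.298 without DHT (adjusted p = 0.000256 and 0.0401) and by 1.95 and 1.07 with DHT (adjusted p = 0.000784 and 0.0189). BAMBI, which encodes a decoy receptor, fell by 1.09 ± 0.284 and 0.95 ± 0.284 (adjusted p = 0.0165 and 0.0272). HLA-E and HLA-F were higher with sip300 and DHT, by 0.56 ± 0.174 (adjusted p = 0.0353) and 0.70 ± 0.18 (adjusted p = 0.0122). Another passing HLA-F probe differed by 0.05 (unadjusted limma p not under 0.05). The non-coding gene HCP5 was higher by 1.82 ± 0.28 (adjusted p = 0.000254). IFI27, an interferon-induced gene, was detected on 3 of 4 sip300 arrays and 0 of 4 siNS arrays at both times (adjusted p = 0.0196 and 0.0172).

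The homeobox genes HOXC9 and HOXC13, named among the falls with DHT, were already lower with sip300. They fell with DHT by 2.38 and 1.90 in siNS and by 2.14 and 1.58 in siCBP cells, and with sip300 in the absence of DHT by 1.96 ± 0.255 (adjusted p = 7.85e-05) and 1.12 ± 0.241 (adjusted p = 0.00526). With DHT they differed between sip300 and siNS by -0.19 and 0.20 (adjusted p = 0.680 and 0.646). In sip300 cells DHT moved them by -0.61 and -0.58 (adjusted p = 0.700 and 0.687; HOXC13 passed with the replicate block, adjusted p = 0.00658). Their responses were not called as different between arms. The tubulin probes TUBA3C, TUBA3D and TUBA3E rose with DHT in siNS cells by 1.5, 1.01 and 1.27 and in siCBP cells by 1.75, 0.92 and 1.47, and fell with sip300 under DHT by 2.38, 1.69 and 2.14. These paralogs are nearly identical, so their probes may read the same transcripts (the call for TUBA3E in siNS cells missed the threshold with no filter on dim probes, adjusted p = 0.0715). TUBB4A, a neuronal tubulin gene, rose with sip300 by 1.67 ± 0.334 and 1.99 ± 0.334. Among genes that conjugate androgens to glucuronic acid, UGT2B28 rose with sip300 and DHT by 2.40 ± 0.693 (adjusted p = 0.0232). UGT2B17 differed by 4.10 ± 1.49 without passing the test (adjusted p = 0.0688, and 4.84e-06 with the replicate block).

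Among lists that passed in no comparison in the fit without a block, the lowest adjusted p was 0.490 for p53 targets, 0.299 for NF-kB targets, 0.389 for CREB and immediate early genes, 0.126 for basal epithelium, 0.112 for stroma, 0.288 for neuroendocrine cells and 0.167 for androgen-repressed genes. A gene measured by more than 1 probe gave a further check. Of 87 other probes of 72 named and called results, 83 had the same sign and 69 of these also an unadjusted p under 0.05, and 0 had the opposite sign with such a p (limma).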
